A study of Mus musculus with 98 samples.

How the data were processed

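The labels describe 98 samples; 23 of them came with processed files here and 22 were used: 7 RNA-seq libraries of sorted DP thymocytes (3 KO-labelled, 4 WT-labelled), 6 Ribo-seq libraries of thymocytes, 3 TRA and 5 TRD 5′ RACE libraries of thymus and 1 single-cell library. Groups and replicate numbers were taken from the sample titles. ATAC-seq, m6A immunoprecipitation, ChIP-seq, HTGTS, chromosome conformation, TRB RACE and the remaining TRA and TRD RACE samples were not analysed here, and the labels list 1 single-cell sample, KO-labelled. The tests, their samples, the gene lists, the alternatives and the naming of genes were fixed before the data were examined; alternatives added later are named as such in the closing part.

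The deposited RNA-seq files hold whole-number counts of reads per gene, closed by counters of reads without a gene that have the form HTSeq writes; the strand setting and the role of each aligner are not given in the sources used here. Reads assigned to no feature made up 52.8% to 56.5% of the total of gene, ambiguous and unassigned counts and were left out of library sizes. Per the submitters' processing notes, the series used fastp 0.20.0, HISAT2 2.2.1, StringTie 2.2.1, Bowtie2 2.4.5, Picard 2.22.8, SAMtools 1.9, bedtools 2.29.2, deepTools 3.5.0, MACS2 2.2.4, HOMER 4.11, Trimmomatic, DESeq2 1.38.3 and edgeR 3.40.2 on mm10, with no role stated for each. Per the file headers, the deposited Ribo-seq counts came from featureCounts 2.0.1 with GENCODE M23 over coding sequence per gene, without strand, from primary alignments of mapping quality 10 or more, in one command over 8 alignments; the folder in that header names DP cells, while the labels say thymocytes. The RACE tables, as deposited, give the count of reads per CDR3 clonotype and its fraction of the file; the program that made them is not given in the sources used here, no molecular identifier is named, and the fraction was used only to check totals. The single-cell matrix, per the file headers, holds UMI counts from Cell Ranger 7.1.0; the labels describe 10x Genomics 3′ v3.1 chemistry with a target of about 10000 cells, and the matrix held 14000 barcodes. Gene IDs were matched to symbols in a table of names for 98.65% of the RNA-seq and 97.9% of the Ribo-seq IDs. No reference genome was used here.

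RNA-seq and Ribo-seq counts were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): TMM factors, filterByExpr, glmQLFit and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment at 0.05; no replicate block was used because the labels do not pair the animals. The interaction of genotype and assay was tested in one edgeR model over the 13 libraries. The 22 gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated one, and each list was also adjusted alone. DESeq2 1.42.0 was the other tool. The median log2 fold change of all genes moved by less than 0.1 under the other scalings. Region shares, repertoire measures and list scores were compared by exact permutation of the libraries on the absolute difference of group means, two-sided. Clonotypes per V family and J segment with at least 10 clonotypes over the libraries were tested with edgeR, V and J apart; with 1 WT-labelled TRA library the spread comes from the KO-labelled pair. For mean log2 CPM of Traj segments 0.5 counts were added. List scores are means of log2 CPM (prior count 1) centred on the mean of each gene. Coding lengths are the summed lengths in the Ribo-seq tables, of which 76.8% were multiples of 3; the trend of each library on length was fitted by loess with span 0.5.

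Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept (13986 of 14000; median 3726 UMIs), scaled to 10000 UMIs, reduced to 2000 variable genes and 30 principal components, and clustered with Leiden at resolution 1 on 15 neighbours (scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0) into 20 clusters. Classes were named from fixed markers; a cluster whose leading genes held more markers of another class, or no clear best class, stayed unnamed. Scrublet called 0 doublets, which over this many cells means that the caller did not work; doublets were in effect kept, and 236 cells had a score above 0.25. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the rest.

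Genes were named by rule: *Mettl3* first; the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM, groups that do not overlap, and a symbol that is no predicted gene, pseudogene, receptor or immunoglobulin segment or mitochondrial gene; the called member of each list with the largest rise and fall, or, with none called, the most abundant member; the 3 largest of each direction for the interaction; and up to 4 called segments per direction. Members given as adjusted over the list alone, *Ifi44*, *Ifit1*, *Irf7*, *Stat2* and *Trbc1* were named after their values were seen, as were *Xist* and the mitochondrial genes of the closing part. The lists cover m6A factors, V(D)J recombination, the receptor complex, *Tcra* locus regulators, enzymes of H3K4me3 and H3K27ac, the BCL2 family, p53 targets, interferon-stimulated genes, cell cycle, selected thymocytes, SOCS genes, double-negative thymocytes, γδ T, NK, B, myeloid, dendritic, erythroid and stromal cells, the integrated stress response, translation factors and ribosomal proteins. Some list members are not reported here.

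Each test was run on simulated data made from the real means and library sizes with 200 changed genes, or 4 changed segments in each of 50 simulations. The RNA-seq test recovered 73% of 2-fold and 93% of 4-fold changes with 11 false calls among 13663 genes, the Ribo-seq test 21% and 88% with 2 among 4902, and the interaction 42% and 92% with 6 among 4836. For segments the shares were 38% and 71% (20 TRA V families), 41% and 78% (43 TRA J segments) and 39% and 74% (15 TRD V families). In Ribo-seq changes of 2-fold were therefore mostly missed. Alternatives covered the scaling, the filter, the tool, the replicate block, each library left out, reads in place of clonotypes, out-of-frame clonotypes, minimum reads, the 5′ region as Traj61-48, clustering resolution and cell filters; their effects are in the closing part.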

Results

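*Mettl3* encodes the catalytic subunit of the complex that writes m6A, a methyl mark on RNA. The series set thymocytes of C57BL/6 mice labelled *Mettl3* knockout (KO) beside wild-type (WT) ones, and its title places the question at the recombination centre of *Tcra*, the locus that double-positive (DP) thymocytes, which carry both CD4 and CD8, rearrange. Poly(A) RNA-seq of sorted DP cells comprised 3 KO-labelled and 4 WT-labelled libraries with 7740797 to 9492555 gene counts. Ribosome profiling (Ribo-seq), which sequences mRNA fragments held by ribosomes, comprised 3 libraries of each genotype from thymocytes with 159362 to 549350 counts, and every KO-labelled library was shallower than every WT-labelled one. 5′ RACE, which amplifies T cell receptor transcripts through the V, CDR3 and J parts, gave 2 KO-labelled libraries and 1 WT-labelled library for TRA and 3 and 2 for TRD. Droplet single-cell RNA-seq covered 1 KO-labelled thymus. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples, part of which may be technical.

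*Mettl3* (ENSMUSG00000022160.18) was read first in each sample. In DP RNA-seq it stood at 89.5, 87.1 and 85.4 CPM (counts scaled to the library size) in the KO-labelled libraries and at 79.9, 91.4, 82.3 and 89.0 CPM in the WT-labelled ones. Its log2 fold change was 0.03 (SE 0.09, adjusted p = 0.899, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). In Ribo-seq it stood at 28.9, 27.6 and 99.0 CPM against 87.7, 41.1 and 60.1 CPM. Its log2 fold change there was −0.16 (SE 0.48, adjusted p = 0.898 by the same test). The single-cell library held 2760 *Mettl3* UMIs, 34.7 CPM over all cells. The part of the gene that was deleted is not given in the sources used here, and a total over the whole gene may count transcript outside it, so these totals check no label. Genotypes are called KO-labelled and WT-labelled throughout.

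In sorted DP cells, interferon-stimulated genes stood higher in the KO-labelled libraries. *Iigp1*, an interferon-induced GTPase, rose from 2.89 ± 0.593 CPM (SD, n = 4) to 15.4 ± 7.97 CPM (n = 3), a log2 fold change of 2.40 (SE 0.36, adjusted p = 0.0402 by edgeR). *Rtp4*, an interferon-induced receptor transporter, rose by 2.01 (SE 0.36, adjusted p = 0.0470 by edgeR), from 13.5 ± 4.05 to 54.3 ± 35.1 CPM, and *Oasl1*, of the oligoadenylate synthetase family, by 1.69 (SE 0.24, adjusted p = 0.0402 by edgeR). Of 24 measured members of the interferon list, 2 rose over all genes tested (*Rtp4* and *Ifit2*, the latter by 0.53) and 23 rose adjusted over the list alone. The median log2 fold change of the list was 0.88, with *Ifi44* at 2.31, *Ifit1* at 1.81 and *Irf7* at 0.96. *Stat2* at −0.14 was the single member below 0. The list ranked above other genes by camera with a preset correlation of 0.01 (adjusted p = 1.57e-20). That call was lost with an estimated one (adjusted p = 0.476 with an estimated correlation). Its mean score per library was higher in 3 of 3 KO-labelled libraries than in any WT-labelled one (exact permutation p = 0.0286, two-sided, the smallest that 35 relabellings give; 0.236 adjusted over 22 lists).

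**Figure D1:**
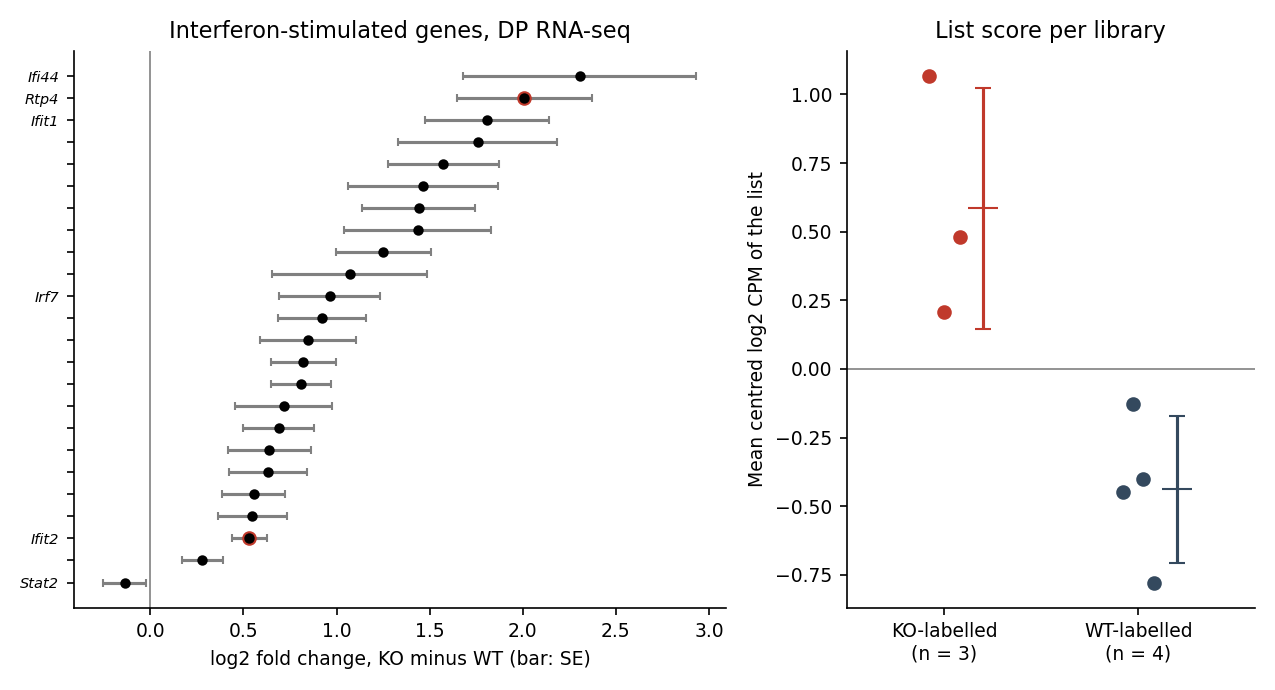
Left, log2 fold change of the 24 interferon-stimulated genes in DP RNA-seq, KO-labelled minus WT-labelled, with bars of 1 SE and red rings on the 2 genes called over all genes tested; the median is 0.88. Right, the mean centred log2 CPM of the list in each library, with the mean and SD of each group beside it (n = 3 and n = 4).

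Across the transcriptome of DP cells, 43 genes rose and 17 fell of 13663 tested (edgeR quasi-likelihood test, two-sided, adjusted p under 0.05). Beside *Iigp1*, *Rtp4* and *Oasl1*, the largest rises were *Tstd1*, a sulfurtransferase gene, at 1.77, *Ticam2*, an adaptor of Toll-like receptor signalling, at 1.46, and *Col20a1*, a collagen gene, at 1.28. The largest falls were *Jup*, which encodes plakoglobin, by 1.42 (from 128 ± 26.8 to 47.7 ± 7.71 CPM), *Car2*, a carbonic anhydrase gene, by 1.28, *Prkcz*, an atypical protein kinase C gene, by 1.21, and *Tnk2os*, an antisense transcript, by 1.10. *Gramd3* fell by 0.97 (SE 0.11; 75.1 ± 6.51 to 38.3 ± 1.30 CPM) and *Fndc9* by 0.95. Because the strand setting of the counting is not given in the sources used here, the value of *Tnk2os* cannot be separated from its sense partner. *Notch3*, a receptor of early thymocytes, rose by 0.69 (SE 0.12, adjusted p = 0.0445 by edgeR) from 76.1 ± 3.07 to 122 ± 20.7 CPM. In 2199 genes (16.1%; 5.71% by chance) the groups did not overlap. The edgeR count fell to 0 without KO-labelled library 1 or WT-labelled library 1, 2 or 3 (1504, 2370, 2305 and 1726 genes at an unadjusted p under 0.05), to 1 without KO-labelled library 2 and to 3 without WT-labelled library 4, and rose to 127 without KO-labelled library 3. DESeq2 called 467 genes, 252 higher and 215 lower.

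Genes of early thymocytes and, in part of the libraries, of proliferation stood higher in KO-labelled DP cells. Of 27 cell cycle genes 26 had a log2 fold change above 0 (median 0.29, camera adjusted p = 8.17e-07, and adjusted p = 0.532 with an estimated correlation). The mean cell cycle score of KO-labelled library 3 (−0.126) lay below those of WT-labelled libraries 1 to 3, and the exact permutation p was 0.2 (0.387 adjusted over 22 lists). Of the list, 4 rose adjusted over the list alone, *Mki67* (0.41), *Aurkb* (0.52), *Birc5* (0.74) and *Cdc6* (0.47), while 0 passed edgeR over all genes. Of 11 double-negative stage genes, *Notch3* rose over all genes and 4 rose adjusted over the list alone (median 0.62, camera adjusted p = 7.88e-05, and adjusted p = 0.476 with an estimated correlation), *Notch3*, *Il2ra* (1.34), *Ptcra* (0.45) and *Mycn* (0.72). Among 9 γδ T cell genes (median 0.72, camera adjusted p = 8.80e-05, and adjusted p = 0.476 with an estimated correlation), *Trdc* (0.53), *Tcrg-C1* (1.52) and *Tcrg-C2* (1.73) rose adjusted over the list alone. Of 20 m6A writers, erasers and readers (median 0.12, camera adjusted p = 0.0167, and adjusted p = 0.476 with an estimated correlation), 5 rose adjusted over the list alone, among them *Wtap* (0.50) and *Ythdf2* (0.52). *Hnrnpa2b1*, the most abundant, did not change (0.10). The 77 ribosomal protein genes had a median of 0.34 (camera adjusted p = 5.84e-08, and adjusted p = 0.586 with an estimated correlation, *Rpl4* 0.34), and KO-labelled library 3 scored below WT-labelled libraries 1 and 2. The 19 enzymes of H3K4me3 and H3K27ac had one of −0.05 (camera down, adjusted p = 0.0169, and adjusted p = 0.476 with an estimated correlation, *Kmt2d* −0.39), and edgeR called 0 members of either list.

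Markers of other cells differed between libraries, although DP cells had been sorted, and did not separate the genotypes for every list. Myeloid and NK scores of KO-labelled library 3 lay below those of WT-labelled libraries 1 and 2 (exact permutation p = 0.229 each), and the selected-cell score of KO-labelled library 2 lay below those of WT-labelled libraries 1 to 3 (exact permutation p = 0.543). Camera placed higher the 14 myeloid markers (median 1.07, adjusted p = 0.00560), 9 NK and innate markers (median 1.00, adjusted p = 0.00250, *Gzma* rose by 1.07 adjusted over the list alone), 7 B cell markers (median 0.49, adjusted p = 0.0202) and 21 genes of selected thymocytes (median 0.27, adjusted p = 0.0448, *Gimap6* −0.12). With an estimated correlation none of the 11 lists passed (1 list, the interferon-stimulated genes, at an unadjusted p of 0.0350): adjusted p = 0.476 with an estimated correlation for the B cell list, 0.532 for NK, 0.586 for myeloid markers and 0.764 for selected thymocytes. KO-labelled library 1 had the highest mean score of other-cell markers (1.15) and WT-labelled library 4 the lowest (−1.91), against −0.309 to 0.433 in the others. These markers were the B cell, myeloid, NK, dendritic and erythroid lists. Leaving out the highest KO-labelled and the lowest WT-labelled library lowers their differences by construction. Smaller medians of these lists without the pair therefore carry no weight. Without this pair, myeloid (−0.02), NK (0.05), B cell (0.19), selected-cell (−0.08) and ribosomal protein (0.06) medians lost the call, as did the m6A (0.07) and histone enzyme lists (−0.08, no nearer 0 than before). Interferon-stimulated (median 0.57, adjusted p = 1.87e-20), γδ (0.41, adjusted p = 2.48e-05), double-negative (0.38, adjusted p = 0.000749) and cell cycle genes (0.13, down from 0.29, adjusted p = 0.00589) kept the call by camera at the preset correlation. These lists had not been used to pick the pair. With all libraries none of them passed (adjusted p = 0.476 with an estimated correlation for the first 3 and 0.532 for cell cycle). The 4 erythroid markers, which had been used to pick the pair, turned lower (−0.68, adjusted p = 0.0160 by camera at the preset correlation). With all libraries their median was 0.31 (camera adjusted p = 0.782 with an estimated correlation). *Xist* was at 0 and 0.119 CPM in KO-labelled library 1 and WT-labelled library 1, and at 1697 to 2691 CPM in the other libraries.

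Genes of the rearrangement machinery did not pass the test in DP RNA-seq. *Rag1*, a subunit of the recombinase, stood at 5138 ± 1144 CPM in KO-labelled and 7154 ± 830 CPM in WT-labelled libraries (log2 fold change −0.48, SE 0.16, adjusted p = 0.184 by edgeR), and the 18 V(D)J recombination genes had a median of 0.01 (camera adjusted p = 0.861). The 17 genes of the receptor complex had a median of 0.00 (adjusted p = 0.420, *Cd8a* 0.00), where *Ptcra* rose adjusted over the list alone. The 22 regulators of the *Tcra* locus had one of −0.06 (adjusted p = 0.118, *Satb1* 0.02). Camera also left uncalled BCL2-family genes (median 0.10, adjusted p = 0.420, *Mcl1* 0.14), p53 targets (0.12, adjusted p = 0.07895, *Trp53inp1* 0.03), SOCS genes (0.21, adjusted p = 0.0816, *Socs4* 0.23, exact permutation p of the score 0.0286 and 0.236 adjusted over 22 lists), stress response targets (0.05, adjusted p = 0.364, *Ddit4* 0.75), translation factors (0.14, adjusted p = 0.190, *Eef1a1* 0.35). Markers stayed uncalled for dendritic (0.66, adjusted p = 0.07895, *Ccr9* 0.03), erythroid (0.31, adjusted p = 0.419, *Hbb-bs* 0.27) and stromal cells (median −0.01 and mean 0.10, adjusted p = 0.775, *Pecam1* −0.01).

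Rearranged and germline *Tcra* transcripts were read next in the same DP libraries, by the share of all Traj counts on each part of the J array. Traj61-41, the 5′ end next to the V segments, held 26.98 ± 6.89% of Traj counts in KO-labelled and 17.5 ± 1.43% in WT-labelled libraries, higher in 3 of 3 (difference 9.49 percentage points, exact permutation p = 0.0286, two-sided, the smallest that 35 relabellings give; 0.162 adjusted over 17 measures). Traj20-2, the 3′ end, held 40.9 ± 10.2% against 50.3 ± 2.23% (exact permutation p = 0.114) and Traj40-21 held 18.9 ± 2.92% against 19.99 ± 1.03% (exact permutation p = 0.486). Total Traj counts came to 261 to 677 per KO-labelled library and 547 to 1004 per WT-labelled one, 48.6 ± 21.3 against 83.5 ± 24.5 CPM (exact permutation p = 0.171). Trav counts came to 121 ± 15.1 against 153 ± 5.25 CPM (exact permutation p = 0.0286; 0.162 adjusted over 17 measures), and the Trav17-21 families next to the J array held 10.8 ± 3.22% against 9.20 ± 0.813% of them (exact permutation p = 0.486). On the scale of mean log2 CPM per segment the 5′ Traj difference was −0.38 (exact permutation p = 0.457), the reverse of the share in sign. On that scale Traj40-21 differed by −0.91 (exact permutation p = 0.0571) and Traj20-2 by −1.45 (exact permutation p = 0.0857). All regions thus stood lower in KO-labelled libraries, and the 5′ region by the least. Without Traj61-59, segments that TRA clonotypes hardly used, the share differed by 5.50 points (exact permutation p = 0.0857).

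In the TRA repertoire, 5′ J segments took a larger share of the clonotypes of both KO-labelled libraries. Traj61-41 held 44.7% (exact 95% interval 43.2 to 46.2) and 36.5% (35.01 to 38.02) of in-frame clonotypes, against 24.6% (23.7 to 25.5) in the WT-labelled library. Traj20-2 held 14.9% and 18.8% against 29.9%, and Traj40-21 held 40.4% and 44.7% against 45.5%. With 2 libraries against 1 no exact permutation p can fall below 0.333, so the difference of 16.02 points in Traj61-41 is a value beside the spread of the KO-labelled pair. The Trav17-21 families held 7.57% and 5.58% against 3.81%. The intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

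**Figure D2:**
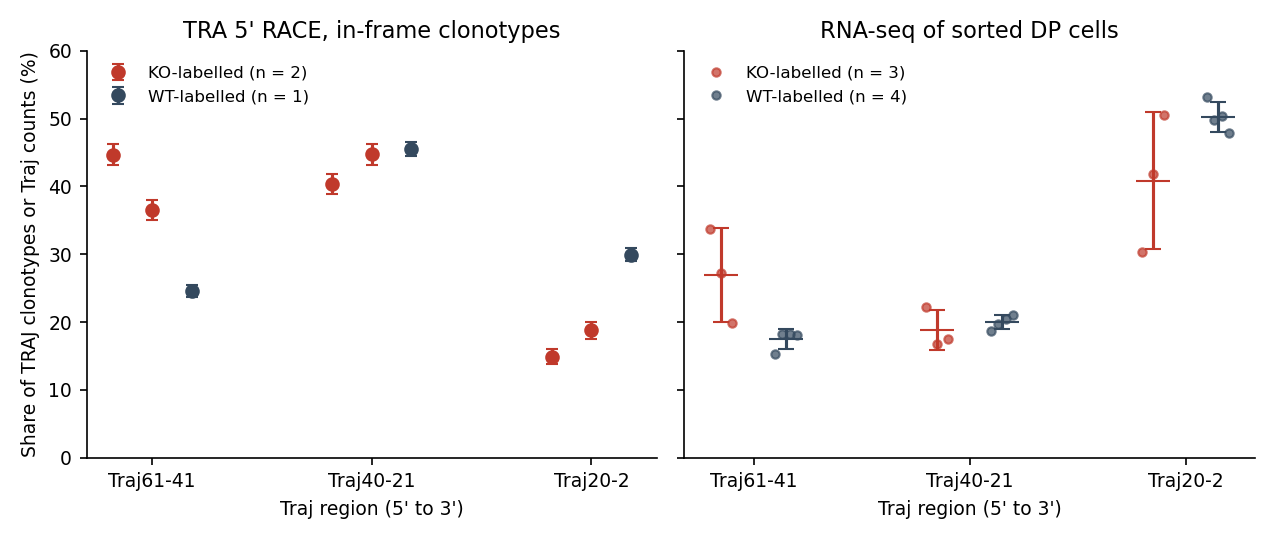
Share of TRA clonotypes (left; bars are exact 95% intervals of each library) and of Traj counts in DP RNA-seq (right; points are libraries, bars the mean and SD) on the 3 regions of the Traj array, from 5′ to 3′. Traj61-41 takes 44.7% and 36.5% of the KO-labelled clonotypes and 24.6% of the WT-labelled ones.

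Among single segments, TRAJ53 held 3.88% and 2.44% of KO-labelled clonotypes against 1.25%, TRAJ58 3.88% and 2.57% against 1.35%, TRAJ56 5.47% and 3.601% against 2.13%, and TRAJ50 3.27% and 2.67% against 1.44%. At the 3′ end TRAJ4 held 1.07% and 1.18% against 3.09%, and TRAJ2 0.464% and 0.797% against 1.88%. Of the V families, TRAV7 held 14.6% and 15.1% against 17.8%. These segments led the 10 that edgeR marked of 43 J segments and 20 V families, but with a lone WT-labelled library, assumed to vary as the KO-labelled pair does, the marks are no test of genotype. Rarefied to 4629206 reads, the KO-labelled libraries held 5422 and 5052 clonotypes against 11765, and the Shannon entropy, scaled from 0 to 1, was 0.955 and 0.952 against 0.971. The draw equalled all TRA reads of the WT-labelled library, and clonotypes had a median of 1796.5 and 1140 against 381 reads. Rarefying reads thus does not even out the cells or RNA put in. CDR3s averaged 13.7 and 13.7 against 13.6 amino acids, and 25.3% and 21.2% against 22.7% of clonotypes were out of frame or held a stop. Every TRA measure had a smallest possible exact permutation p of 0.333. The file under the label of TRA KO replicate 3 repeated that of TRD KO replicate 3 (3547 clonotypes, 71 with counts that differ, by at most 2 reads) and was not used for TRA.

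In the TRD repertoire no V or J segment passed the test. TRDV2-2 led with 38.4 ± 1.94% of in-frame clonotypes (n = 3) against 42.3 ± 2.75% (n = 2, exact permutation p = 0.3). It was followed by TRAV15 with 24.5 ± 4.73% against 20.4 ± 0.569% (exact permutation p = 0.3), TRDV5 with 11.4 ± 1.43% against 9.76 ± 0.896% (exact permutation p = 0.3) and TRDV1 with 9.54 ± 2.57% against 9.26 ± 0.850% (exact permutation p = 1). TRDJ1 made up 99.15 ± 0.115% and 99.1 ± 0.260%. Of 15 V segments and 2 J segments, edgeR called 0, also at an unadjusted p under 0.05. Rarefied to 2941164 reads the libraries held 2620 ± 630 against 1248 ± 639 clonotypes (exact permutation p = 0.2), again without evening out the cells or RNA put in. CDR3s averaged 18.04 ± 0.326 against 18.3 ± 0.0395 amino acids (exact permutation p = 0.4). The nonproductive share was 50.6%, 29.4% and 27.8% in KO-labelled libraries 1 to 3 against 30.4% and 36.6% (exact permutation p = 1), where 1507 clonotypes of KO-labelled library 1 had a single read. Its mean was 35.9 ± 12.7% against 33.5 ± 4.40% and the scaled entropy 0.906 ± 0.0549 against 0.910 ± 0.00413 (exact permutation p = 1). No exact permutation p can fall below 0.1 here, and all 21 adjusted values were 0.63 or higher.

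Ribo-seq of thymocytes gave fewer ribosome-held fragments of *Trac* and of genes of selected thymocytes in the KO-labelled libraries. *Trac*, the constant part of TCRα, fell by 1.39 (SE 0.26, adjusted p = 0.0161 by edgeR), from 727 ± 105 to 278 ± 84.4 CPM (n = 3 each), and *Itm2a*, a gene induced in positive selection, by 1.17 (SE 0.28, adjusted p = 0.0441 by edgeR), from 464 ± 85.8 to 206 ± 68.5 CPM. *Lat*, the adaptor below the receptor, rose by 1.23 (SE 0.29, adjusted p = 0.0441 by edgeR) and *Trp53inp1*, a p53 target, by 1.68 (SE 0.22, adjusted p = 0.00380 by edgeR), from 432 ± 43.3 to 1390 ± 198 CPM. In all, 54 genes rose and 27 fell of 4902 tested, and 12 rose and 19 fell with the trend on coding length removed. The largest rises were *Prelid1* (3.49, SE 0.66), of mitochondrial lipid transfer, the histone gene *Hist2h2ab* (2.91), and *Mrpl14* (2.65), of the mitochondrial ribosome. They were followed by *Atp5j* (2.55, SE 0.40, adjusted p = 0.00627 by edgeR), of ATP synthase, *Atp6v1f* (2.43), of the proton pump of lysosomes, and *Txnl4a* (2.11), of the spliceosome. The largest falls were *Masp2* (−3.17, SE 0.63), a complement protease gene, *Ighg2b* (−2.85), *Fmnl2* (−1.92), *Poc1b* (−1.90), *C3* (−1.90), of complement, and *Mr1* (−1.77, SE 0.32, adjusted p = 0.0141 by edgeR), which presents antigen to MAIT cells. Histone copies are near-identical, so the value of *Hist2h2ab* is uncertain.

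By list in Ribo-seq, 13 of 14 genes of selected thymocytes had a log2 fold change below 0 (median −0.78, camera adjusted p = 1.68e-05, adjusted p = 0.300 with an estimated correlation). *Itm2a* fell over all genes and 7 fell adjusted over the list alone, among them *Il7r* (−1.46), *Cd5* (−0.86) and *Itgae* (−0.92). Cell cycle genes stood higher (24 measured, median 0.54, adjusted p = 0.000281, and adjusted p = 0.4999 with an estimated correlation; 0 called by edgeR), as did ribosomal proteins (14 measured, median 0.43, adjusted p = 0.0218, and adjusted p = 0.4999 with an estimated correlation; 4 rose adjusted over the list alone). With the trend on coding length removed the ribosomal protein call was lost (median 0.14, adjusted p = 0.526, 0 adjusted over the list alone), and cell cycle genes kept theirs (0.56, adjusted p = 2.81e-05). Dendritic markers stood lower (5 measured, median −0.94, adjusted p = 0.0218, and adjusted p = 0.430 with an estimated correlation), and *H2-Aa* (−0.98), *H2-Eb1* and *Cd74* (−1.05) fell adjusted over the list alone. Of 16 receptor complex genes *Lat* rose and *Trac* and *Trbc1* fell over all genes (median −0.11, camera adjusted p = 0.265), with *Trbc2* the third to fall adjusted over the list alone. With the trend on coding length removed that list passed as lower (median −0.27, adjusted p = 0.0118), and adjusted p = 0.560 with an estimated correlation and the trend kept. Interferon-stimulated genes had a median of 0.20 over 11 members (adjusted p = 0.278), which edgeR left uncalled.

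**Figure D3:**
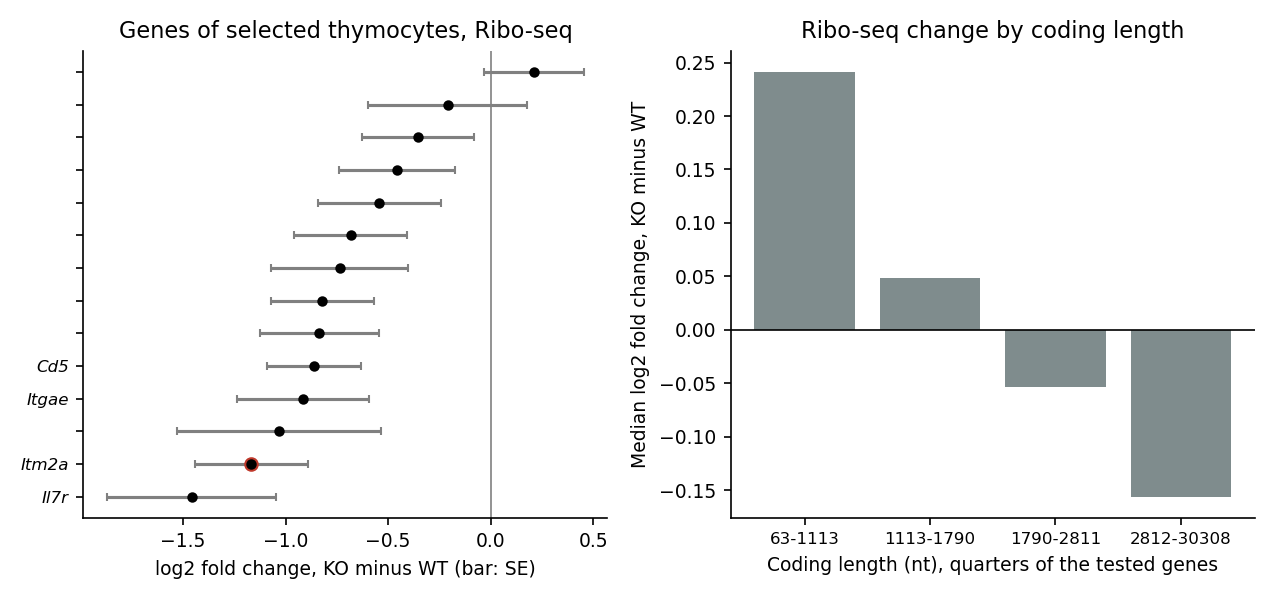
Left, Ribo-seq log2 fold change of the 14 measured genes of selected thymocytes, KO-labelled minus WT-labelled, with bars of 1 SE and a red ring on *Itm2a*; 13 lie below 0. Right, median log2 fold change of all tested genes in bins of coding length, from 0.24 in the shortest to −0.16 in the longest.

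The remaining lists did not pass camera in Ribo-seq with the coding length trend kept. *Hnrnpa2b1*, an m6A reader, stood at 8260 ± 1480 against 4162 ± 1814 CPM (0.99, adjusted p = 0.0721 by edgeR) and rose adjusted over the list alone, in a list of 19 with a median of 0.23 (adjusted p = 0.209), and *E2f2* did so among 21 *Tcra* locus regulators (median 0.05, adjusted p = 0.899, *Satb1* −0.04). V(D)J recombination genes had a median of 0.05 (adjusted p = 0.661, *Rag1* 0.29), histone mark enzymes −0.19 (adjusted p = 0.265, *Kmt2d* 0.20), p53 targets −0.03 against a mean of 0.19 (adjusted p = 0.265), double-negative genes −0.09 against a mean of 0.16 (adjusted p = 0.661, *Notch1* −0.09), translation factors 0.28 (adjusted p = 0.0720, *Eif3a* 0.14) and myeloid markers −0.88 (adjusted p = 0.0704, *Cst3* −0.21), where *Mpeg1* and *S100a8* fell adjusted over the list alone. With the trend removed myeloid markers passed as lower (median −1.21, adjusted p = 0.00364), and adjusted p = 0.4999 with an estimated correlation and the trend kept. In the stress response list (8 measured, median 0.05, adjusted p = 0.976) the cystine transporter *Slc7a11* fell by 1.61 over all genes (adjusted p = 0.0461 by edgeR) and *Shmt2* rose adjusted over the list alone. *Bcl2l1* fell by 1.17 adjusted over the list alone in a BCL2 list of 2 measured genes (adjusted p = 0.278, *Mcl1* 0.13). *Trdc* (0.09), *Gzma* (0.54), *Ighm* (−0.41) and *Pecam1* (−0.08) were the single measured members of the γδ, NK, B cell and stromal lists, and no SOCS or erythroid gene was deep enough to test.

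Ribo-seq values also moved with coding length and with single libraries. The log2 fold change fell with coding length (Spearman −0.291 across genes, which are not independent), and called genes had a median coding length of 651 when higher and 1378 when lower, against 1807 in the others. With each library's length trend removed, a check added after the data were seen, 31 genes were called, 27 of them among the 81, including *Prelid1*, *Mrpl14*, *Atp5j*, *Masp2*, *Mr1*, *Trac*, *Trp53inp1* and *Itm2a*. The call was lost for *Lat* (0.92, SE 0.29, adjusted p = 0.124 by edgeR), *Hist2h2ab* (2.45), *Atp6v1f* (2.03), *Txnl4a* (1.69), *Ighg2b* (−2.95), *Fmnl2* (−1.80), *Poc1b* (−1.92), *C3* (−1.73) and *Slc7a11* (−1.63). All were still at an unadjusted p under 0.05, which does not show how much of each fold went with length. The rises among them shrank, *Lat* from 1.23, *Hist2h2ab* from 2.91, *Atp6v1f* from 2.43 and *Txnl4a* from 2.11. Of the falls, *Fmnl2* and *C3* shrank and the others did not. Fewer genes were called with the trend removed, which makes the adjustment stricter at a given p. *Ighg2b*, *Poc1b* and *Slc7a11* lost the call in that way, not by a weaker effect. Of the 54 rises called with the trend kept, 45 lay in the shortest bin of coding length (63 to 1113) and 0 in the longest (2812 to 30308). These bins held 9 and 6 of the 27 falls. Selected-cell genes kept a median of −0.81 (camera adjusted p = 2.73e-07, and adjusted p = 0.300 with an estimated correlation and the trend kept). The edgeR count was 0, 10 and 34 without KO-labelled library 1, 2 or 3 and 592, 5 and 3 without WT-labelled library 1, 2 or 3 (643 genes at an unadjusted p under 0.05 where it was 0), and DESeq2 called 112. With all genes of at least 1 count kept, 112 rose and 113 fell. In 1143 genes (23.3%; 10% by chance) the groups did not overlap.

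Set against the RNA-seq of DP cells in one edgeR model, the genotype effect differed between the assays in 74 of 4836 genes, 47 with the higher effect in Ribo-seq and 27 with the lower. *Prelid1* (3.57, SE 0.53, adjusted p = 0.00280), *Atp5j* (2.49) and *Mllt1* (2.35), a gene of transcription elongation, had the largest positive differences, and *Masp2* (−3.34), *Poc1b* (−2.07) and *Thap12* (−1.97) the largest negative ones. *Trac* differed by −1.29 (SE 0.28, adjusted p = 0.0270 by edgeR), with a log2 fold change of −0.09 in RNA and −1.39 in Ribo-seq. The model gave each gene a single spread for both assays. For *Prelid1* the SE of the difference (0.53) lay below that of the Ribo-seq effect alone (0.66). The same held for *Mllt1* (0.37 against 0.46), *Atp5j*, *Poc1b* and *Thap12*, though not for *Masp2* or *Trac*. The noise of Ribo-seq was thus understated for such genes, and the 74 calls may be too confident. Selected-cell genes (median difference −1.06, camera adjusted p = 2.25e-05) and myeloid markers (−1.98, adjusted p = 0.0130) had lower effects in Ribo-seq, both with adjusted p = 0.839 with an estimated correlation, and dendritic markers did not pass (−1.62, adjusted p = 0.0830). Over all their members in DP RNA-seq, the medians of selected-cell genes and myeloid markers were 0.27 and 1.07. Without KO-labelled library 1 and WT-labelled library 4 they were −0.08 and −0.02. Myeloid markers had been used to pick these 2 libraries, so their drop was built in. The difference between assays was not tested without that pair. Of the genes tested in both assays, 0 were called in both (0.260 by chance from 17 and 74 calls). In Ribo-seq, 54 of the 74 called genes (73.0%) had the same sign in RNA. The same share over all genes was not taken, and the effects correlated across all genes (Spearman 0.238). The share is therefore given as a value only. The RNA came from sorted DP cells and the Ribo-seq label names thymocytes, so the difference is not a translational efficiency of one population. The count ranged from 11 to 551 as single libraries were left out. With genes filtered at a mean CPM of at least 1 in both assays it was 20, of which 8 had the higher effect in Ribo-seq and 12 the lower.

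In the KO-labelled single-cell library, DP-like cells made up 53.7% of 13986 cells (exact 95% interval 52.9 to 54.5), counting a cluster of 242 that scored highest for DP and next for cycling genes and was led by genes such as *Cenpa* and *Ccnb2*, of mitosis. Cycling-like cells made up 15.9%, cells like signalled DP or early selected thymocytes 11.5%, CD4 SP-like cells 5.22%, CD8 SP-like cells 2.85%, NK or NKT-like cells 1.29% and DN-like cells 0.758%, and 8.84% fell in clusters left unnamed. *Rag1* was at 1291 CPM in DP-like cells (1278 to 1305), 318 in signalled cells and 127 in CD4 SP-like cells, and *Trac* at 520, 1132 and 940 CPM. *Bcl2l1*, a survival factor of DP cells, was at 422 CPM in DP-like and 153 CPM in signalled cells. *Mettl3* ranged from 27.1 CPM (25.3 to 29.1) in cycling-like to 44.2 CPM (39.5 to 49.3) in signalled cells. *Trgc1*, *Trgc2* and *Trgc4* were among the leading genes of the DN-like cluster. With 1 library no genotype was compared, and the Poisson intervals of CPM and exact binomial intervals of shares cover counting error only.

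**Figure D4:**
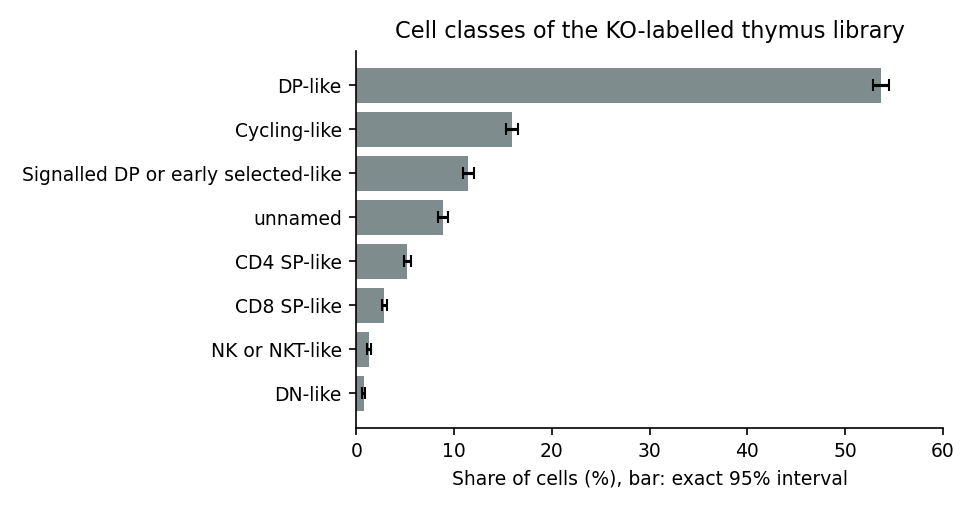
Share of the 13986 cells of the KO-labelled thymus library in each class, with exact 95% binomial intervals; DP-like cells lead with 53.7%.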

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

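The tests of sex for the interferon-stimulated genes, of coding length for the selected-cell genes and of Traj61-59 were set out before their results were seen, and out-of-frame clonotypes and single TRA libraries left out were set alternatives, though the use of the former as a test of selection was not. The test of the difference between the assays was also fixed beforehand. All other tests in this part, including every regrouping of the libraries, were chosen only after the result was seen.

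Interferon-stimulated genes stood higher in KO-labelled DP cells, with a median log2 fold change of 0.88 over 24 genes. Without the libraries highest and lowest in other-cell markers the median was 0.57, without KO-labelled library 1 it was 0.62, and with sex as a factor 0.85, which argues against other-cell RNA, a single library or sex as the whole cause. Of the 35 splits of the libraries, 1, the genotype split, gave a difference of the mean score this large. An interferon response of the KO-labelled thymi may account for it; exposure or housing of single animals was not tested.

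Ribo-seq changes went with coding length as well as with genotype. With the length trend removed, 27 of the 81 called genes stayed called, 15 of 27 falls and 12 of 54 rises, and all 81 kept an unadjusted p under 0.05. The median edgeR p of all 27 falls went from 0.000515 to 0.000204. Of the named falls that lost the call, *Fmnl2* (−1.92 to −1.80) and *C3* (−1.90 to −1.73) moved nearer 0, while *Ighg2b*, *Poc1b* and *Slc7a11* did not. *Poc1b* went from −1.90 (SE 0.445) to −1.92 (SE 0.444) and *Slc7a11* from −1.61 (SE 0.393) to −1.63 (SE 0.387). With 31 genes called against 81, the adjustment is stricter at a given p. The lost call of *Ighg2b*, *Poc1b* and *Slc7a11* thus came from the adjustment and does not point to length. The falls had a median of −1.68 (quartiles −1.83 and −1.30), against −1.61 (−1.84 and −1.16) with the trend kept, and selected-cell genes one of −0.81. The trend raised short genes, and both sets were shorter (median coding length 1378 and 1189) than the uncalled genes (1807). Its removal could therefore hardly shrink their falls, so this check could not have shown length as the cause. What argues against length as the whole cause of both is the direction of the trend, which would raise them. The median of the rises went from 1.48 (1.21 and 1.82) to 1.12 (0.95 and 1.52), which leaves length undecided for them. Over genes called without WT-labelled library 1 that library lay at 0.41 of the way from the KO-labelled mean to the other WT-labelled ones, but a library left out of the choice of genes falls short by that choice alone, so depth stays untested. A smaller share of selected cells in the KO-labelled thymi could lower these genes, and cell shares were not measured in the Ribo-seq samples.

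5′ Traj segments took a larger share of TRA clonotypes in the KO-labelled libraries, by 16.02 percentage points. The difference was 16.3 with shared CDR3s kept only where they had most reads, 16.9 among clonotypes of at least 10 reads and 18.02 among out-of-frame clonotypes. These values argue against clonotypes of few reads and carry-over between the libraries used here as the whole cause. Libraries without usable files could not be checked for carry-over. Out-of-frame clonotypes make no receptor, so the last value argues against selection on their own protein. A cell can hold an in-frame receptor from its other allele, so selection of cells was not excluded. The difference was 11.9 to 20.1 with 1 KO-labelled library left out. In DP RNA-seq the share without Traj61-59 differed by 5.50 points, which leaves reads on these segments undecided as a cause there. Fewer successive rearrangements per allele, or shorter-lived DP cells, might give such a shift, and the lone WT-labelled library keeps its own error inside the difference.

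The libraries were also regrouped without regard to genotype. For DP genes 1 of 35 splits, the genotype split, reached its 60 calls and the highest other gave 0. That is the smallest share that 35 splits can give, and the regrouping was chosen after the count was seen. With single libraries left out the count ran from 0 to 127, so chance is made less likely but is not excluded. For DP gene lists 14 of 35 splits reached the 11 called lists and the highest other called 15, so chance cannot be excluded. The 10 splits of Ribo-seq are too few for a share under 0.05: 1 reached the 81 called genes (highest other 13) and 5 reached the 4 called lists (highest other 5). For the difference between assays 5 of 100 labellings, the genotype one included, reached 74 calls, so chance cannot be excluded. The highest other labelling gave 622, and the cause of that was not tested.

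Values of single libraries that stood apart were sought with Dixon's test in the 4 WT-labelled DP libraries, where chance alone gives about 1 in 20 groups; 7 of 78 groups had one (3.9 by chance), 3 of them WT-labelled library 4. They were *Pecam1* in library 4 (164 CPM; others 145 to 148), the score of H3K4me3 and H3K27ac enzymes in library 2 (−0.018; others 0.09 to 0.11), the scores of selected-cell genes (−1.53; others 0.16 to 0.33) and SOCS genes (−0.51; others −0.06 to −0.02) in library 4, the Traj61-41 share in library 1 (15.4%; others 18.1 to 18.3%), the Trav3-16 share in library 3 (90.3%; others 88.3 to 88.6%) and the gene counts of library 3 (7740797; others 8597872 to 8688921).

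The effect in Ribo-seq differed from that in DP RNA-seq in 74 genes, led by *Prelid1* (3.57), *Atp5j* (2.49), *Mllt1* (2.35), *Masp2* (−3.34), *Poc1b* (−2.07) and *Thap12* (−1.97), with *Trac* at −1.29. These calls may be too confident, since a single spread per gene was fitted over both assays. The TRD libraries held TRAJ clonotypes that were not analysed as a repertoire: 1525, 43 and 661 in KO-labelled libraries 1 to 3 and 264 and 653 in WT-labelled libraries 2 and 3. The file under TRA KO replicate 3 shared all 3547 clonotypes with that of TRD KO replicate 3.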

How the results depend on the processing

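The alternatives with a coding length trend removed, sex as a factor, Traj61-59 left out, the repeated file's TRAJ clonotypes, a minimum of 10 reads, a pair of libraries or any single library left out of the lists, and a doublet score bound were chosen only after the result was seen.

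The DP gene count of 60 became 467 with DESeq2 (252 higher, 215 lower), 516 with no filter beyond 1 count, 33 at an absolute log2 fold change of 1 or more, 196 with sex as a factor and 563 with a replicate block that the labels do not support, and 0 to 127 with single libraries left out. The 11 DP lists became 0 with an estimated correlation, 5 without KO-labelled library 1 and WT-labelled library 4, and 7 to 13 with single libraries left out. The pair had been picked on markers of other cells, which favours the loss of those lists. The 5′ Traj difference of 9.49 points was 6.12 to 13.0 with single libraries left out, 5.50 without Traj61-59, and turned to −0.38 as mean log2 CPM. On that scale the other Traj regions differed by more (−0.91 and −1.45), so the change of sign goes with lower Traj values throughout. Trav17-21 ran from −0.30 to 2.65. The cause of the other movements was not tested.

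The Ribo-seq gene count of 81 became 31 with the length trend removed (12 higher, 19 lower), 45 with that and a replicate block (17 higher, 28 lower), 50 with a replicate block alone, 256 at a mean CPM of 1 or more, 225 with no filter beyond 1 count, and 0 to 592 with single libraries left out; its 4 lists became 0 with an estimated correlation. The 74 genes that differed between assays (47 higher, 27 lower) became 20 at a mean CPM of 1 or more in both (8 higher, 12 lower) and 46 with a replicate block in each assay. The count was 11 to 551 with single Ribo-seq libraries left out (49 without KO-labelled library 3, 25 and 12 without KO- and WT-labelled library 2, 13 without KO-labelled library 1). Without RNA-seq libraries it was 28 and 25 (KO-labelled 2 and 3) and 36, 30 and 27 (WT-labelled 1 to 3). Deviations of same-numbered KO- and WT-labelled libraries, whether paired or not, correlated at 0.495, −0.0165 and 0.286 in DP RNA-seq and at −0.102, −0.198 and 0.0612 in Ribo-seq. In DP RNA-seq KO-labelled library 1 correlated best with its own number. KO-labelled library 3 did so among WT-labelled libraries 1 to 3, but correlated more with library 4 (0.330), which has no KO-labelled partner. KO-labelled library 2 correlated more with WT-labelled library 3 (0.0656) than with its own number. The labels name no pairs, so the numbers are not read as pairs, but a batch that goes with the number is not excluded. The cause of the movements was not tested.

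The difference in TRA CDR3 length of 0.0775 amino acids was 0.0867 at 10 or more reads and 0.0497 weighted by reads. The 10 TRA segments became 0 with the TRAJ clonotypes of the repeated file as a KO-labelled library. Of these 661 clonotypes 602 were also in the WT-labelled TRA library, so that loss was built in and carries no weight. The TRD segments went from 0 to 1 by reads. The DP-like share of 53.7% was 45.5% at Leiden resolution 0.5, 52.2% at 2, 52.5% with at least 1000 genes, 50.8% with up to 20% mitochondrial UMIs and 49.9% without cells of a doublet score above 0.25.

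Genes near 0 changed sign as single libraries were left out. In DP RNA-seq *Ccr9* ran from −0.010 to 0.073, *Cd8a* from −0.043 to 0.047 (−0.0060 with DESeq2, −0.0076 with its size factors), *Cst3* from −0.090 to 0.41, *Hbb-bs* from −0.33 to 0.71 (−0.17 with a replicate block), *Mettl3* from −0.0045 to 0.060, *Pecam1* from −0.068 to 0.085 (0.017 by library size, 0.027 with a replicate block), *Satb1* from −0.034 to 0.085, *Trp53inp1* from −0.038 to 0.090 and the Trav3-16 share from −2.36 to 0.800 points. In Ribo-seq *Ccr9* ran from −0.24 to 0.039, *Cst3* from −0.52 to 0.15, *Kmt2d* from −0.073 to 0.75, *Mcl1* from −0.22 to 0.48, *Mettl3* from −1.11 to 0.14, *Notch1* from −0.38 to 0.22, *Pecam1* from −0.30 to 0.065, *Rpl22* from −0.11 to 0.15, *Satb1* from −0.12 to 0.030 and *Trdc* from −0.21 to 0.48.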

Other observations

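All observations in this part were chosen only after the result was seen.

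Mitochondrially encoded genes gave fewer Ribo-seq counts in the KO-labelled libraries: 5 of 7 fell, with a median log2 fold change of −1.64 (−1.75 with the length trend removed) and *mt-Nd1*, a subunit of complex I, at −2.62, against a median of 0.22 in DP RNA-seq. Their share of Ribo-seq counts was 0.375%, 0.269% and 0.438% in KO-labelled libraries and 0.569%, 1.52% and 1.21% in WT-labelled ones. The depths in the same order were 226920, 159362 and 254072 counts and 293212, 510949 and 549350 counts. Within the KO-labelled libraries the share rose with depth, and the shallowest WT-labelled library had the lowest WT-labelled share. Genotype and depth can therefore not be told apart for these genes. Of 49 histone genes 5 rose (median 0.80), and 1 with the length trend removed (median 0.27).

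In the single-cell library a cluster of 35 DP-like cells was led by *Rsad2*, *Usp18*, *Ddx60* and *Ifit1*, and *Cdkn1a*, a p53 target, was at 62.7 CPM in DN-like and 0.419 CPM in DP-like cells.

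Of the 661 TRAJ clonotypes in the TRD library of KO replicate 3, 602 (91.1%) were also in the TRA library of WT replicate 3, as were 544 of 653 (83.3%) from the TRD library of WT replicate 3. The TRA library of KO replicate 2 held 25 of 43 (58.1%) from the TRD library of KO replicate 2 and 132 of 264 (50%) from that of WT replicate 2, and the TRA library of KO replicate 1 held 283 of 1525 (18.6%) from the TRD library of KO replicate 1. Sharing thus followed the replicate number across genotype labels. For numbers 2 and 3 the same TRA library shared with TRD libraries of both labels. That argues against a swapped label alone, provided that the labels stand for separate animals, which is not stated. Carry-over between libraries was not tested directly. The TRA comparison sets numbers 1 and 2 against number 3, so whatever goes with the number stays inside it.

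Counts of the Y-linked genes *Kdm5d*, *Eif2s3y*, *Uty* and *Ddx3y* were 0 in Ribo-seq WT-labelled library 2 and present in the other libraries, a mark of the sex of the animals, which also varied among the DP libraries by *Xist*.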
